A study of Mus musculus with 4 samples.

How the data were processed

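The data were droplet single-cell RNA profiles of mouse hematopoietic stem cells (HSCs) from C57BL/6 bone marrow. The labels name 4 libraries in 2 groups: 2 libraries of HSCs aged in a young niche and 2 of HSCs aged in an old niche. Per the labels, the authors made the libraries with 10x Chromium chemistry (3' kit, V2) and ran bcl2fastq and then Cell Ranger 2.1.0 against the mm10 genome. The deposited matrices hold UMI counts per gene and cell barcode, without normalization, which was checked on the values (whole numbers, with totals that differ between cells and libraries). Per the file names the matrices are the filtered ones, so the authors had already called cells. The version of bcl2fastq, the annotation release and the settings of cell calling are not given in the sources used here.

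Cells were kept with at least 500 genes detected and under 10% of UMIs from mitochondrial genes. Of 22689 barcodes, 324 were removed and 22365 kept. UMI counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were taken in scanpy 1.11.5. Cells were clustered on shared neighbours with leidenalg 0.10.2 at resolution 0.5, without integration across libraries. Clusters were named "X-like" from 17 marker lists written before the data were examined. A list named a cluster when its markers had the highest mean log2 fold over the mean of the other clusters, with a pseudocount of 10 CPM. At least 3 markers had to be up 2-fold, and no other list could hold more of the 10 leading genes. This scoring was chosen after the data were seen. HSC-like cells were clusters 0, 1, 2 and 7, and megakaryocyte-like cells were clusters 3, 5, 6 and 8. Clusters 13 and 15 stayed unnamed.

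For tests, the UMI counts of a gene were summed over the cells of a library, so each library gave 1 value. The comparison of 2 libraries with 2 was made over all kept cells and within each class with at least 50 cells in every library. Genes passed edgeR's filterByExpr, library sizes were scaled by TMM, and edgeR 4.0.16's quasi-likelihood test was used with Benjamini-Hochberg adjustment and a threshold of 0.05. Folds are log2 values of the old niche over the young niche. The standard error (SE) is the size of the fold divided by the square root of the F statistic. Levels of genes are CPM on TMM-scaled library sizes, and levels of marker lists are CPM of all UMIs without TMM. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

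The 27 gene groups were also written before the data were examined. They were tested with camera from limma 3.58.1 on log CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 27 groups. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. Simulated counts had the same fitted spread per gene in both groups, whereas in the data the old niche libraries differed more from each other. The recovery rates hold for that setting only. On 200 simulated changed genes with the fitted spread, the HSC-like test recovered 0% of 1.5-fold, 31.9% of 2-fold and 93% of 4-fold changes. The test over all kept cells recovered 0%, 26.8% and 87.5% of them. Unchanged genes were called too: 7 in the HSC-like test, 5 in the test over all kept cells and 11 in the megakaryocyte-like test. In a further simulation the interferon response group was raised 1.5-fold, with genes drawn independently. Camera with the preset correlation called it. Of 26 unchanged groups, the same test also called 2 in all kept, 0 in HSC-like and 1 in megakaryocyte-like cells. With an estimated correlation, 0 unchanged groups were called. Camera's adjusted p for the raised group was then 0.0853 in all kept, 0.517 in HSC-like and 0.112 in megakaryocyte-like cells. Camera with an estimated correlation can therefore miss a true change of that size.

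Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals, and groups of libraries were compared by a two-sided exact permutation test. The 4 libraries can be split into pairs in 3 ways, so the smallest p that test can give is 0.333. For shares of cells with a UMI, every cell was thinned to 1500 UMIs and cells below that depth were left out. This removed 0 cells from the young niche libraries, 750 from old niche replicate 1 and 145 from old niche replicate 2. A share of 0 is given with the limit that 3 counts allow. Intervals and limits cover counting error only.

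Named genes followed a rule fixed before the data were examined. For all kept cells and for HSC-like cells, it took the 10 largest rises and 10 largest falls among genes past the threshold, with a mean of at least 10 CPM and both old niche libraries on the same side of both young niche libraries. It added up to 4 such members per gene group, 19 genes named whatever their result, and the genes of smallest p where fewer than 10 passed. This gave 96 genes for all kept cells, of which 80 passed, and 40 for HSC-like cells, of which 20 passed. Of the 19, 1 gene is not reported here. Genes described outside this rule were chosen after their values were seen. Coordinates are GRCm38 (mm10) from GENCODE vM21, which held 27645 of the 27998 gene IDs in the tables. The other 353 had no coordinates.

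The alternatives covered scaling, the filter on low counts, each library left out, a replicate block, the cell filters and likely doublets by Scrublet score (0.8% per 1000 barcodes). They also covered clustering, depth, abundant genes, the thinning depth, and other tests (DESeq2 1.42.0, limma, fry and camera with an estimated correlation). Alternatives chosen after seeing the data were cells with Xist and no Y-linked UMI, clusters found in each library alone, tests without genes of likely free RNA, and gene groups under further cell and cluster choices. Other tools were Python 3.11.15, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.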

Results

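Transcripts of single HSCs that had aged in a young or an old niche were counted in 4 libraries, 2 per group. The question was how the niche in which HSCs age is reflected in their transcripts. The young niche libraries held 9550 and 2935 barcodes with 71446292 and 22261936 UMIs, at a median of 6379 and 6727 UMIs per barcode. The old niche libraries held 4403 and 5801 barcodes with 9626841 and 21006482 UMIs, at a median of 1968 and 3309. Depth per cell therefore followed the groups. Among genes of at least 10 CPM in HSC-like cells, the log2 ratio of the 2 young niche libraries had an SD of 0.172, against 0.0926 between 2 random parts of 1 library. For the 2 old niche libraries it was 0.447, against 0.147. Cells with Xist and no Y-linked UMI made up 52.7% and 52.1% of the young niche libraries, 54.2% of old niche replicate 1 and 95.4% of old niche replicate 2. Cells with Y-linked UMIs and no Xist made up 16.5%, 20.2%, 7.88% and 0.139% in the same order. Cells with neither made up 24.7%, 24.5%, 36.2% and 4.38%, so their sex could not be read.

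Cells with the transcript profile of HSCs formed 55.6% ± 1.52 (SD, n = 2) of kept cells from the young niche and 81.9% ± 14.1 (SD, n = 2) from the old niche. Their share was 54.6% (95% exact binomial interval 53.5 to 55.6) and 56.7% (54.9 to 58.5) in the young niche libraries. It was 91.9% (91.0 to 92.7) and 71.9% (70.7 to 73.1) in the old niche libraries. Megakaryocyte-like cells, led by Pf4, Gp1bb and Itga2b, took 27.4% ± 0.732 and 12.4% ± 10.3 (SD, n = 2 each). Their shares were 28.0% (27.1 to 28.9) and 26.9% (25.3 to 28.6) in the young niche libraries and 5.14% (4.49 to 5.85) and 19.7% (18.7 to 20.8) in the old niche libraries. Neutrophil-like cells, led by Ngp, Camp and S100a9, took 10.6% ± 1.67 and 1.14% ± 0.427 (SD, n = 2 each), a mean of 9.5 points less in the old niche. Myeloid-progenitor-like cells took 2.69% ± 0.0126 and 0.869% ± 0.118, and erythroid-like cells 1.68% ± 0.00563 and 0.787% ± 0.136 (SD, n = 2 each).

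Plasma-like cells with Jchain and Mzb1 formed 2.72% (2.31 to 3.17) of old niche replicate 2 and 0.333% (0.182 to 0.559) of old niche replicate 1, against 0.105% (0.0506 to 0.194) and 0.0688% (0.00833 to 0.248) in the young niche. T-cell-like cells took 0.353% ± 0.23 and 0.628% ± 0.753, and unnamed clusters 1.29% ± 0.612 and 0.642% ± 0.537 (SD, n = 2 each). B-cell-like cells took 0.194% ± 0.0658 of the young niche libraries (SD, n = 2) and 0.208% (0.107 to 0.363) of old niche replicate 2. In old niche replicate 1 there were 0 of 4201 cells, which allows a share of up to 0.0714%. Both old niche libraries lay on one side of both young niche libraries for HSC-like, megakaryocyte-like, neutrophil-like, myeloid-progenitor-like, erythroid-like and plasma-like cells. That gives an exact two-sided permutation p of 0.333, the smallest the design allows. For erythroid-like cells this was lost with at least 1000 genes per cell. Their share was then 1.41% and 1.38% in the young niche libraries and 1.51% and 0.929% in the old niche libraries. With clusters found in each library alone, the mean difference in the HSC-like share was 4.6 points instead of 26.2, with an exact permutation p of 1.0. In that setting 29.3% of old niche replicate 2 stayed unnamed. Its largest unnamed cluster, of 1437 cells, scored highest for the HSC list, but another list held more of its 10 leading genes. With clusters of each library alone, megakaryocyte-like cells took 32.4% and 27.5% of the young niche libraries and 29.4% and 15.4% of the old niche libraries (exact permutation p = 0.667), so the low share in old niche replicate 1 was not kept. At resolution 1.0 the megakaryocyte-like share of old niche replicate 2 was 0.242%.

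**Figure D1:**
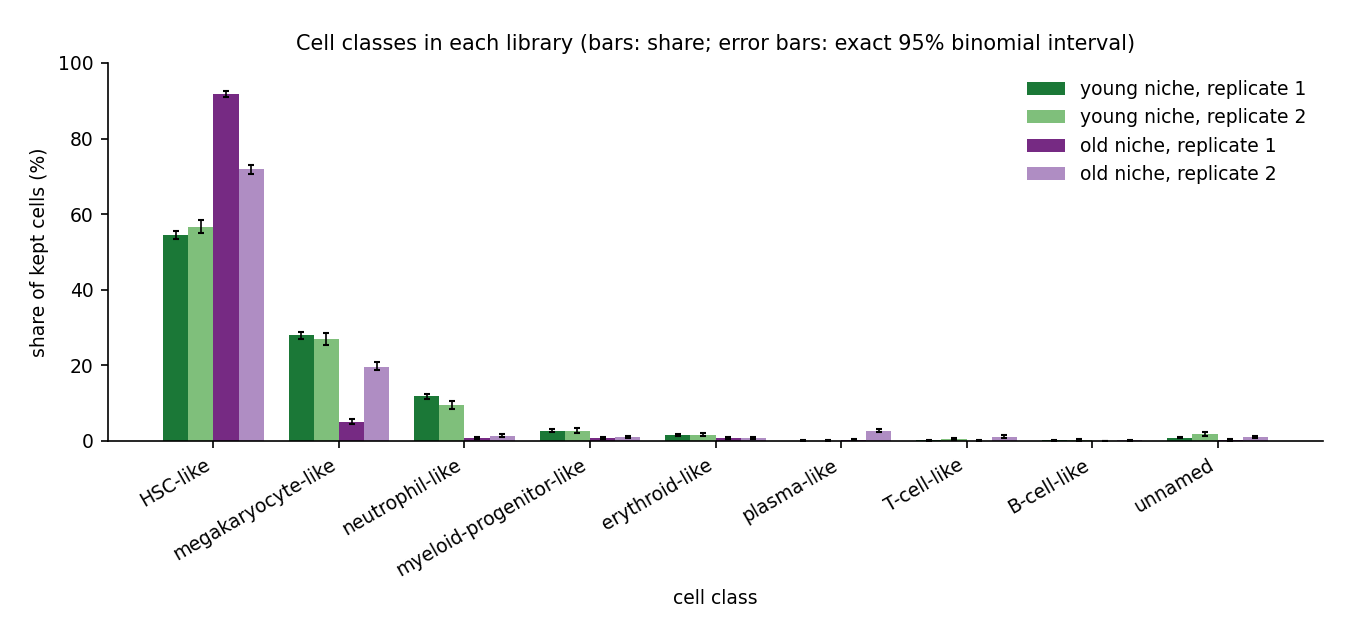
Share of kept cells (%) in each class, 1 bar per library with its exact 95% binomial interval; green bars are young niche libraries and purple bars old niche libraries. HSC-like cells take 54.6% and 56.7% of the young niche libraries and 91.9% and 71.9% of the old niche libraries.

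Across all kept cells, Mecom and Kit were among the genes higher in the old niche libraries. Mecom, a transcription factor needed to maintain HSCs, rose from 76.0 ± 4.67 to 205 ± 24.9 CPM (SD, n = 2 each), a log2 fold of 1.47 ± 0.149 (SE). Mecom (ENSMUSG00000027684) lies on chromosome 3 from 29951296 to 30548008. Kit, the receptor of stem cell factor, rose from 69.4 ± 0.0743 to 136 ± 8.36 CPM (SD, n = 2 each). Kit (ENSMUSG00000005672) lies on chromosome 5 from 75574916 to 75656722. The largest rises by the naming rule were in Unc45b, a myosin chaperone (log2 fold 2.98 ± 0.19), and Matn4, an extracellular matrix protein (2.76 ± 0.159). They went on with the long non-coding RNA Snhg9 (2.70 ± 0.268), the imprinted RNA Meg3 (2.61 ± 0.372), Dennd5b (2.56 ± 0.133) and the lipoprotein receptor Vldlr (2.55 ± 0.374). E130102H24Rik (2.42 ± 0.344), Tsix, the antisense transcript of Xist (2.30 ± 0.342), Cebpb (2.09 ± 0.35) and Lag3 (1.98 ± 0.191) completed the 10. Errors are SE with n = 2 libraries per group.

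Cdkn2a and genes of neutrophils were among those lower in the old niche libraries. Cdkn2a, which encodes inhibitors of cell division, fell from 28.1 ± 1.68 to 0.452 ± 0.342 CPM (SD, n = 2 each), a log2 fold of -5.66 ± 0.324 (SE). Cdkn2a (ENSMUSG00000044303) lies on chromosome 4 from 89274471 to 89294653. The p53 targets Phlda3 and Cdkn1a fell by 2.99 ± 0.191 and 2.33 ± 0.263 (log2 and SE). The neutrophil genes Chil3 (-4.38 ± 0.265), S100a9 (-3.26 ± 0.245) and S100a8 (-3.21 ± 0.213) fell. So did Cryab, a small heat-shock protein (-3.72 ± 0.179), Gkn3 (-3.52 ± 0.31) and the protease Ctse (-3.25 ± 0.162). AA467197 (-3.52 ± 0.25), Clec4a2 (-3.31 ± 0.169) and Ifitm6 (-3.26 ± 0.149), a leading gene of a neutrophil-like cluster, fell too. Like Chil3, S100a9 and S100a8, they had at least 10 times the HSC-like level in another class. Their falls therefore cannot be told apart here from the change in class shares. Pf4, a platelet chemokine, fell from 1000 ± 124 to 195 ± 8.09 CPM, and Cxcr4, the receptor that binds the niche chemokine Cxcl12, from 39.4 ± 0.711 to 10.2 ± 3.32 (SD, n = 2 each). Adjusted p for the genes of these 2 paragraphs lay between 0.00528 and 0.0378 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each had both old niche libraries on one side of both young niche libraries.

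In all, 841 of 13034 genes passed in all kept cells, 341 higher and 500 lower in the old niche. Without a scaling factor the split was 521 higher and 337 lower, and the median log2 fold of all genes moved from 0.0445 to 0.166. Without genes of likely free RNA it was 268 higher and 294 lower of 12319 tested. In cells with Xist and no Y-linked UMI it was 355 higher and 365 lower of 12591. The count was 381 and 467 without young niche replicates 1 and 2, and 6779 and 3921 without old niche replicates 1 and 2. Of 19 genes named whatever their result, Mecom, Kit and Selp passed and 16 did not, among them Procr (0.16 ± 0.121), Slamf1 (0.19 ± 0.172), Hlf (0.88 ± 0.244), Cd34 (0.95 ± 0.245), Cdk6 (1.00 ± 0.407) and Mki67 (-0.22 ± 0.425), given as log2 fold ± SE.

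By camera, 11 of the 27 gene groups passed in all kept cells, and with an estimated correlation 0 did. Of the 52 tested genes of G2 and M phase, 20 fell and 0 rose (36 and 0 adjusted over the list alone), among them Ube2c (-1.89 ± 0.16), Psrc1 (-1.79 ± 0.148) and Birc5 (-1.57 ± 0.152), with a camera adjusted p of 4.6e-17 (0.476 with an estimated correlation). Of 42 S-phase genes, 10 fell and 0 rose (25 and 0 adjusted over the list alone), led by Rrm2 (-1.71 ± 0.132), with adjusted p = 4.7e-11 (0.476 with an estimated correlation). Of 29 genes of myeloid priming, 12 fell and 2 rose (15 and 3 adjusted over the list alone), with adjusted p = 2.3e-06 (0.476 with an estimated correlation). Hp (-2.55 ± 0.35) and Igsf6 (-2.38 ± 0.293) fell, while Cebpb rose. Among cells with Xist and no Y-linked UMI this group was not lower, at a camera adjusted p of 0.597 in the upward direction. Of 30 genes of erythroid priming, 5 fell and 0 rose (14 and 1 adjusted over the list alone), with adjusted p = 1.4e-04 (0.476 with an estimated correlation). Of 30 p53 targets, 5 fell and 0 rose (8 and 0 adjusted over the list alone), with adjusted p = 0.00132 (0.476 with an estimated correlation). Of 78 nuclear genes of oxidative phosphorylation, 5 fell, Cox5a among them (-0.98 ± 0.154), and 0 rose (6 and 0 adjusted over the list alone), with adjusted p = 2.6e-08 (0.509 with an estimated correlation).

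Of 40 HSC identity genes, 5 rose and 1 fell (9 and 2 adjusted over the list alone), with adjusted p = 1.4e-04 (0.476 with an estimated correlation). Mecom, Prdm16 (1.04 ± 0.165) and Kit rose and Gfi1b (-1.02 ± 0.131) fell. Of 50 niche receptors and adhesion genes, 8 rose and 3 fell (14 and 4 adjusted over the list alone), with adjusted p = 0.0157 (0.476 with an estimated correlation). Notch2 (1.08 ± 0.169) and Alcam (1.04 ± 0.121) rose and Cxcr4 (-1.96 ± 0.238) fell. Of 32 platelet genes, 4 fell and 1, Selp (0.63 ± 0.126), rose (13 and 3 adjusted over the list alone), with adjusted p = 0.0246 (0.476 with an estimated correlation). A further group held immediate early genes and genes of cell dissociation, heat-shock genes included. Of its 37 tested genes, 6 fell, such as Hsp90aa1 (-1.38 ± 0.15), and 3 rose, such as Socs3 (1.77 ± 0.217) and Egr1 (1.24 ± 0.132). Adjusted over the list alone, 12 fell and 4 rose, with adjusted p = 0.040 for the group (0.476 with an estimated correlation). The 4 hemoglobin genes had a camera adjusted p of 0.00827 (0.509 with an estimated correlation), with 0 past the threshold by edgeR and 4 lower adjusted over the list alone. The first p of each pair is from camera with the preset correlation. By fry, 3 groups passed: HSC identity (higher), platelet genes (lower) and transforming growth factor and bone morphogenetic protein signalling (higher). Markers of neutrophils were at 29800 ± 2340 and 3650 ± 347 CPM in the young and old niche libraries, and those of erythroid cells at 8540 ± 1790 and 2520 ± 1330 (SD, n = 2 each).

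The remaining 16 groups did not pass in all kept cells by camera. Genes reported as higher in aged HSCs had an adjusted p of 0.221 and a median log2 fold of 0.18, with 6 of 57 higher and 2 lower (9 and 7 adjusted over the list alone). Genes reported as lower in aged HSCs had adjusted p = 0.199 and a median of -0.14, with 1 of 29 higher and 2 lower (4 and 7 adjusted over the list alone). Adjusted p was 0.0506 for glycolysis, 0.0724 for transforming growth factor and bone morphogenetic protein signalling, 0.0843 for the interferon response and 0.0913 for the unfolded protein response. It was 0.153 for MHC class I, 0.182 for epigenetic regulators, 0.216 for quiescence and inhibitors of cell division and 0.416 for mitochondrially encoded genes. It was 0.496 for inflammation through NF-kappaB, 0.757 for MHC class II, 0.786 for ribosomal proteins, 0.786 for autophagy, 0.978 for lymphoid priming and 0.978 for sex-linked genes. Median and mean differed in sign for MHC class II and ribosomal proteins, and the test and both of them for sex-linked genes.

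Within HSC-like cells, Matn4 and Dennd5b were higher and Ctse and Gkn3 lower in the old niche, as in all kept cells. The class joins clusters that differ between libraries. The largest held 4489 and 1256 cells of the young niche and 37 and 9 of the old niche. Of the old niche cells, 3756 of replicate 1 and 4080 of replicate 2 lay in a cluster each, with few young niche cells. Matn4 (ENSMUSG00000016995, chromosome 2, 164389393 to 164405160) rose from 5.31 ± 0.392 to 29.0 ± 2.08 CPM (SD, n = 2 each), a log2 fold of 2.48 ± 0.163 (SE). Dennd5b (ENSMUSG00000030313, chromosome 6, 148988071 to 149101680) rose from 18.3 ± 0.915 to 82.7 ± 1.05 CPM (SD, n = 2 each), a log2 fold of 2.19 ± 0.137 (SE). Ctse (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505) fell from 100.2 ± 2.46 to 4.88 ± 0.769 CPM (SD, n = 2 each), a log2 fold of -4.33 ± 0.171 (SE). Gkn3 (ENSMUSG00000030048, chromosome 6, 87383256 to 87388935) fell from 123 ± 1.52 to 7.27 ± 3.5 CPM (SD, n = 2 each), a log2 fold of -4.12 ± 0.337 (SE). In CPM without TMM, Gkn3 was at 197 and 201 in young and 7.45 and 5.18 in old niche cells with Xist and no Y-linked UMI. Cells with Y-linked UMIs and no Xist had 11.5 and 12.8 CPM in the young niche and 8.64 CPM (6 UMIs) in old niche replicate 1. The fall thus lay largely in cells with Xist. Hoxc6, a homeobox gene (ENSMUSG00000001661, chromosome 15, 102998257 to 103011881), fell from 17.9 ± 0.835 to 3.40 ± 0.892 CPM (SD, n = 2 each), a log2 fold of -2.35 ± 0.219 (SE).

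The other rises were in Gm14964 (2.58 ± 0.254), Eid2 (2.57 ± 0.229), Unc45b (2.46 ± 0.241), the linker histone H1fx (1.65 ± 0.131), the deubiquitinase Yod1 (1.61 ± 0.151), the mitochondrial gene mt-Atp8 (1.60 ± 0.148) and Tnrc6c (1.15 ± 0.129). Pcp4l1 (1.22 ± 0.141) filled the 10th place and did not pass (adjusted p = 0.0524, edgeR). The other falls were in Cryab (-3.58 ± 0.197), AC168977.1 (-2.61 ± 0.168), Phlda3 (-2.15 ± 0.241), AC125149.3 (-2.14 ± 0.239), Psma8 (-2.01 ± 0.145), Serpina3f (-2.01 ± 0.159), A530040E14Rik (-1.92 ± 0.201) and the transcription factor Klf6 (-1.40 ± 0.136). Serpina3f has close paralogs, so its reads are less surely assigned. The heat-shock gene Hspa1a, chosen after its values were seen and with a close paralog too, fell by 4.26 ± 0.267 (log2 and SE). Adjusted p for the passing genes lay between 0.00445 and 0.0483 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and each was on the same side in 2 of 2 old niche libraries.

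**Figure D2:**
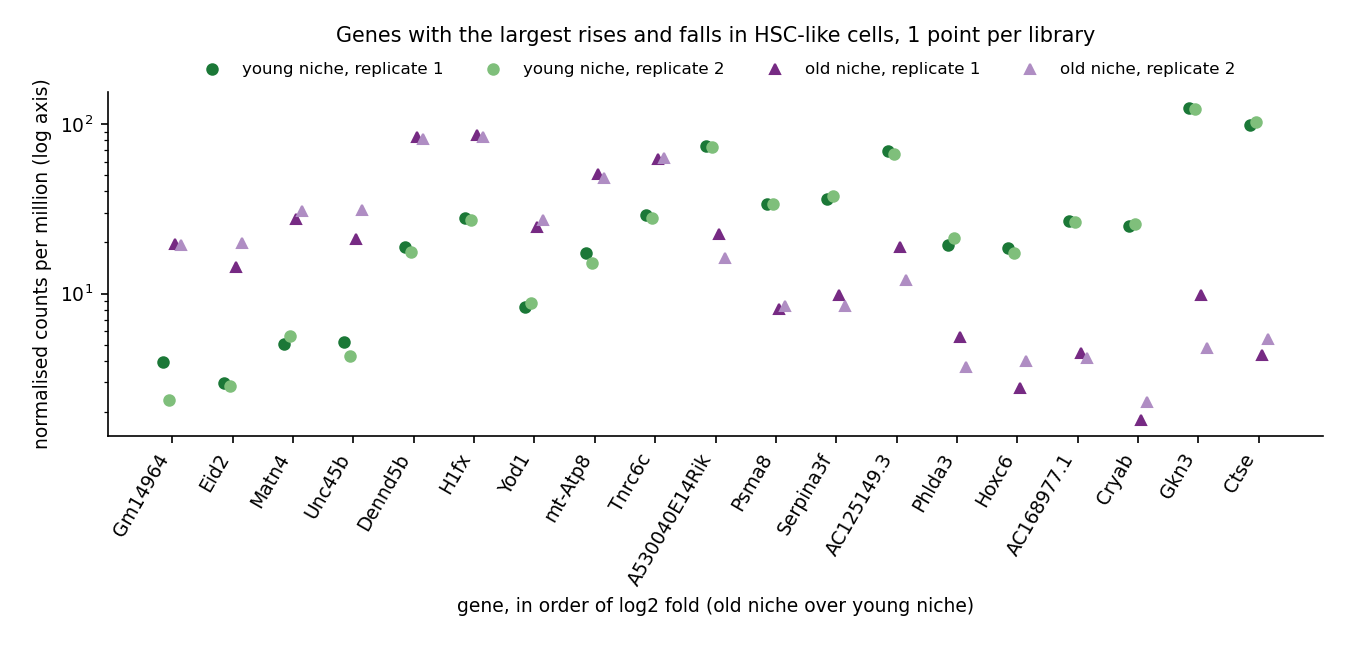
Normalised CPM (log axis) of the named genes with the largest rises and falls in HSC-like cells, ordered by log2 fold, 1 point per library; circles are young niche and triangles old niche libraries. In each gene both triangles lie on one side of both circles, from Gm14964 (log2 fold 2.58) to Ctse (-4.33).

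In HSC-like cells 34 of 12214 genes passed, 16 higher and 18 lower. The count was 134 without a scaling factor (79 higher, 55 lower) and 393 with DESeq2. It was 22 and 12 without young niche replicates 1 and 2, and 5588 and 2501 without old niche replicates 1 and 2. Among cells with Xist and no Y-linked UMI, 140 genes passed, and Hoxc6 was at -0.24 ± 0.519 (adjusted p = 0.809, edgeR). Mecom (1.11 ± 0.146, adjusted p = 0.0672, edgeR), Kit (0.90 ± 0.149, adjusted p = 0.0831) and Cxcr4 (-2.49 ± 0.286, adjusted p = 0.0524) did not pass in HSC-like cells, though each had both old niche libraries on one side of both young niche libraries. Nor did Procr (-0.37 ± 0.185), Slamf1 (-0.01 ± 0.147), Hlf (0.58 ± 0.326) or Xist (0.72 ± 0.265), given as log2 fold ± SE.

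Among gene groups in HSC-like cells, interferon response genes were lower as a set, with a median log2 fold of -0.40 over 53 members and a camera adjusted p of 6.0e-08 (0.698 with an estimated correlation). By edgeR 0 of them passed over all genes tested and 11 were lower adjusted over the list alone. Igtp was at -1.13, Gbp3 at -1.07 and Gbp2 at -0.98. Of 37 genes of the immediate early and dissociation group, 2 fell, Klf6 and Hspa1a, and 0 rose (16 and 3 adjusted over the list alone), with adjusted p = 1.3e-04 (0.584 with an estimated correlation). Of 29 p53 targets, 1, Phlda3, fell and 0 rose (3 and 0 adjusted over the list alone), with adjusted p = 0.00303 (0.584 with an estimated correlation). MHC class I (adjusted p = 0.00303, median -0.40), oxidative phosphorylation (adjusted p = 0.00349, median -0.14), the unfolded protein response (adjusted p = 0.00591, median -0.38) and MHC class II (adjusted p = 0.00778, median -0.21) were lower, with 0 members past the threshold. With an estimated correlation their adjusted p was 0.584, 0.764, 0.584 and 0.584. Adjusted over the list alone, 0, 0, 2 and 3 of their members were lower. Myeloid priming (adjusted p = 0.0392, 8 lower and 3 higher adjusted over the list alone) and glycolysis (adjusted p = 0.0433, 1 and 1) were lower too, at 0.715 each with an estimated correlation, again with 0 members past the threshold. Neutrophil markers moved the same way in these cells, at 2430 and 1250 CPM in the young and 848 and 211 in the old niche libraries. So did dendritic (1600 and 1710 against 1010 and 1190) and monocyte markers (555 and 522 against 381 and 313). Erythroid, myeloid progenitor, B cell and HSC markers were also lower in both old niche libraries. Markers of cycling progenitors (300 and 347 against 463 and 737), mast cells, T cells and stroma were higher in both.

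Epigenetic regulators (adjusted p = 0.0207, median 0.26, 0 members adjusted over the list alone) and niche receptors (adjusted p = 0.0479, median 0.29, 9 higher and 5 lower adjusted over the list alone) were higher, with 0 members past the threshold over all genes. With an estimated correlation adjusted p was 0.715 and 0.584. At an unadjusted p under 0.05, edgeR gave 2655 of the 12214 genes. None of these 11 calls held with an estimated correlation. That test also missed a simulated 1.5-fold change of a whole group in HSC-like cells, so this loss does not decide whether the calls are true. By fry 0 groups passed. The other 16 groups had camera adjusted p from 0.0724, for G2 and M phase (44 tested genes, median -0.18) and for quiescence genes, to 0.991, for platelet genes. S-phase genes had adjusted p = 0.404 and HSC identity genes adjusted p = 0.334. Genes reported as higher or lower in aged HSCs had adjusted p = 0.476 and adjusted p = 0.365. The former had 1 of 56, Matn4, higher (6 higher and 8 lower adjusted over the list alone), and the latter 0 of 29 (1 lower adjusted over the list alone). The median was above 0 and the mean and test below 0 for genes reported as higher in aged HSCs, platelet genes, erythroid priming, NF-kappaB inflammation and hemoglobin.

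**Figure D3:**
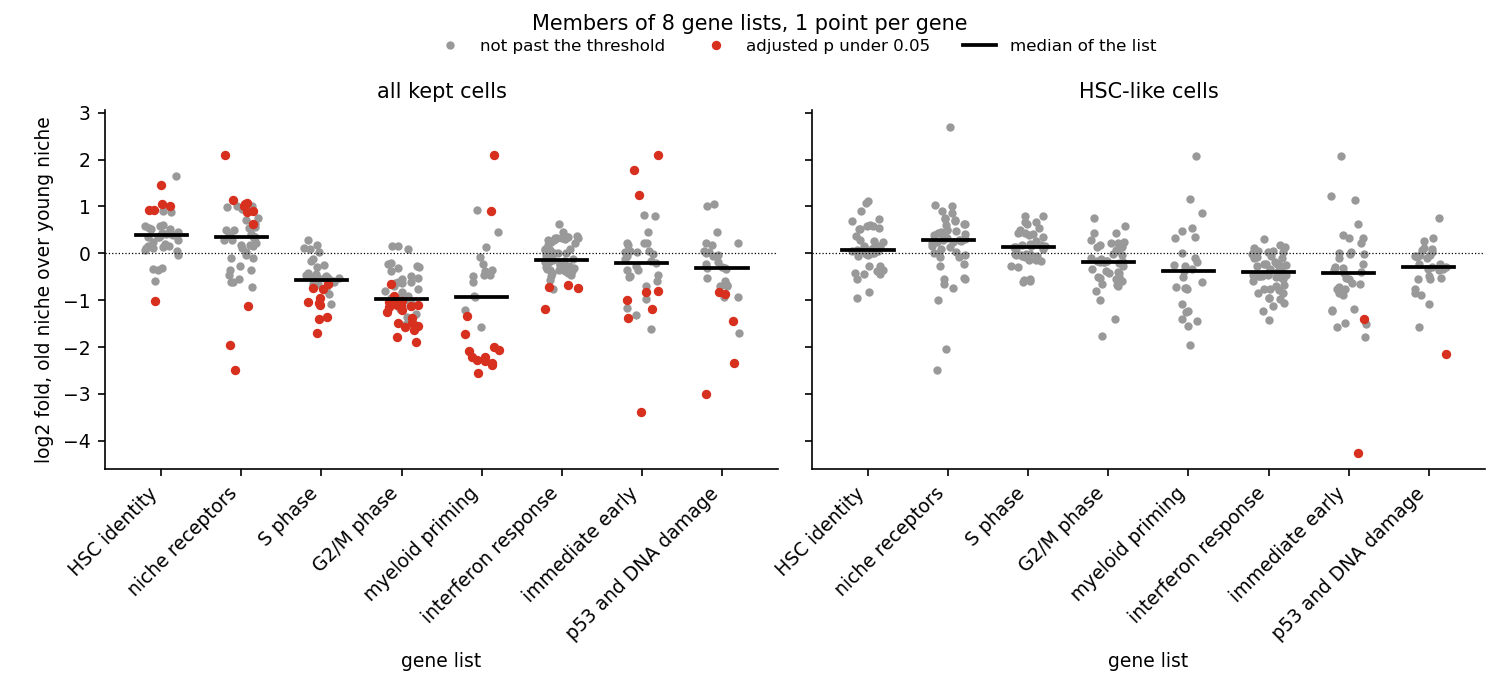
Log2 fold, old niche over young niche, of each tested member of 8 gene groups in all kept cells (left) and in HSC-like cells (right); red points have an adjusted p under 0.05 and black lines are medians. The median of the G2 and M phase group is -0.99 in all kept cells and -0.18 in HSC-like cells.

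Within megakaryocyte-like cells, Phlda3 and Cdkn1a were lower and Mecom and Kit higher in the old niche. Of these cells, 1127 of the 1139 of old niche replicate 2 lay in a cluster that held 2 and 2 cells of the young niche libraries, so the comparison sets different clusters side by side. Cdkn2a was at 59.3 and 53.9 CPM in the young niche libraries and had 0 and 6 UMI-bearing cells of 216 and 1139 in the old niche libraries, before thinning. Phlda3 (-3.83 ± 0.207), Cdkn1a (-2.91 ± 0.198), Ctse (-3.98 ± 0.208) and Gkn3 (-2.57 ± 0.279) fell. H1fx (2.18 ± 0.196), Cd34 (1.55 ± 0.15), Mecom (1.29 ± 0.159) and Kit (1.02 ± 0.177) rose, each with both old niche libraries on one side. Of 39 HSC identity genes 8 rose and 2 fell (14 and 3 adjusted over the list alone), with a camera adjusted p of 0.0244 (0.572 with an estimated correlation). Of 26 genes of quiescence and inhibitors of cell division 4 fell and 2 rose (4 and 3 adjusted over the list alone), with a camera adjusted p of 0.304 (0.582 with an estimated correlation). Of 30 p53 targets 9 fell and 0 rose (11 and 0 adjusted over the list alone), with a camera adjusted p of 3.45e-05 and adjusted p = 0.572 with an estimated correlation. By edgeR 1162 of 11186 genes passed, 816 higher and 346 lower, or 1302 and 276 without a scaling factor. This count is not firm: it was 5 with clusters of thinned cells, 6 with limma, 306 with clusters found in each library alone and 73, 139, 4574 and 557 without each library in turn (young niche replicates 1 and 2, old niche replicates 1 and 2).

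At an equal depth of 1500 UMIs, fewer HSC-like cells of the old niche had a UMI of Gkn3 and more had one of Mecom or Dennd5b. These genes and Cdkn2a were chosen after their values were seen. Gkn3 was found in 10.5% (95% exact interval 9.71 to 11.4) and 10.6% (9.11 to 12.1) of young niche cells and in 1.14% (0.8 to 1.58) and 0.732% (0.495 to 1.04) of old niche cells. In neutrophil-like cells, at the same thinned depth, it was found in 1.34% and 0.727% of the young niche libraries and in 0 of 28 and 0 of 78 cells of the old niche libraries, which allows up to 10.7% and 3.85%. Mecom was found in 15.2% (14.2 to 16.2) and 14.1% (12.5 to 15.9) of young niche cells and 30.2% (28.6 to 31.8) and 32.7% (31.3 to 34.2) of old niche cells, against 1.43%, 1.09%, 7.14% and 1.28% of neutrophil-like cells. Dennd5b was found in 2.46% (2.05 to 2.91) and 2.18% (1.53 to 3.01), against 8.59% (7.63 to 9.62) and 10.2% (9.29 to 11.2). In neutrophil-like cells of the old niche Dennd5b was found in 2 of 28 and 3 of 78. Before thinning the median depths of HSC-like and neutrophil-like cells were 5740 and 4790, 6050 and 5120, 1980 and 1860, and 3130 and 3200 UMIs in young niche replicates 1 and 2 and old niche replicates 1 and 2.

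Cdkn2a was found in 2.90% (2.57 to 3.26) and 2.75% (2.19 to 3.41) of all kept cells of the young niche and in 0.058% (0.00702 to 0.209) and 0.124% (0.05 to 0.256) of the old niche. In HSC-like cells the counts were 81 of 5172 and 25 of 1649 against 1 of 3156 and 0 of 4096, the latter allowing up to 0.0732% of cells with a UMI. In neutrophil-like cells Cdkn2a was found in 0.625% and 0.364% of the young niche libraries and in 0 of 28 and 0 of 78 cells of the old niche libraries. Cells with at least 2 UMIs of the G2 and M phase group, at 1500 UMIs per cell, made up 63.5% ± 1.53 and 48.7% ± 2.43 of all kept cells (SD, n = 2 each). In HSC-like cells they made up 47.0% ± 1.5 and 42.4% ± 0.725, and in megakaryocyte-like cells 81.7% ± 1.49 and 85.6% ± 11.2 (SD, n = 2 each). The group's level was 1110 ± 27.7 and 1010 ± 34 CPM in HSC-like cells, 4780 ± 157 and 5530 ± 1750 in megakaryocyte-like cells and 3540 ± 62.3 and 1920 ± 371 in all kept cells (SD, n = 2 each). Exact permutation p was 0.333 for the differences in all kept and HSC-like cells and 1.0 for those in megakaryocyte-like cells. Free RNA may add to such shares, which was not tested for these genes, so they are not read as cycling alone.

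Markers of other cell types were summed per list and are given in CPM. In all kept cells, as means of the young and old niche libraries with SD (n = 2 each), monocyte markers were at 2070 ± 106 and 526 ± 20.4, platelet markers at 1400 ± 45 and 633 ± 26, and myeloid progenitor markers at 3170 ± 396 and 2350 ± 187. HSC markers were at 2450 ± 5.99 and 3210 ± 485, markers of cycling progenitors at 428 ± 27.4 and 692 ± 271, and lymphoid progenitor markers at 210 ± 3.66 and 108 ± 78. Plasma cell markers were at 261 ± 36.5 and 2370 ± 2830, with 4370 in old niche replicate 2 and 367 in old niche replicate 1. Dendritic markers were at 1190 ± 114 and 1230 ± 339, natural killer cell markers at 161 ± 21.1 and 156 ± 51.8, and endothelial markers at 191 ± 11.4 and 250 ± 62.8. B cell markers were at 88.7 ± 22.8 and 89.0 ± 70.3, T cell markers at 49.7 ± 4.51 and 58.0 ± 8.8, and mast cell and basophil markers at 31.9 ± 21.6 and 27.2 ± 22.2. Eosinophil markers were at 24.9 ± 27.9 and 34.8 ± 36.2, and stromal markers at 5.11 ± 1.51 and 12.7 ± 5.22. Exact permutation p was 0.333, the smallest possible, for the first 7 lists of this paragraph, endothelial and stromal markers, and 0.667 or 1.0 for the others.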

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

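All tests of explanations in this part were chosen only after the results were seen. The test of the difference between HSC-like and megakaryocyte-like cells covered 12379 genes.

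The niche difference itself differed between the 2 classes in 124 genes (94 with the higher log2 fold in megakaryocyte-like cells, 30 with the lower), by edgeR's quasi-likelihood test of the interaction with Benjamini-Hochberg adjustment. Gkn3 fell in both classes, with a log2 fold 1.81 ± 0.276 (SE) higher in megakaryocyte-like cells. Hoxc6 was 2.06 ± 0.394 higher there, at -0.15 against -2.35 in HSC-like cells. Cd34 was 0.588 ± 0.115 higher, and the linker histone H1fx 0.403 ± 0.0895 higher. Phlda3 fell more in megakaryocyte-like cells, with a difference of -1.55 ± 0.31 on the log2 scale. These tests take the classes of 1 clustering, and the megakaryocyte-like class depended on it.

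The first pattern is that cell-cycle and neutrophil genes were lower in the old niche libraries over all kept cells. When every library was given the same mix of classes, the median log2 fold of the G2 and M phase group was 0.192, against -0.85 with the observed mix, so the pattern is consistent with a change in the mix of classes. The classes are partly defined by these genes and join clusters that differ between libraries, which limits that test. The neutrophil markers took a like share of UMIs in HSC-like and megakaryocyte-like cells, with a largest log2 ratio of 0.454 in size. In the young niche they were at 5990 and 3180 CPM in erythroid-like and 2380 and 1470 in T-cell-like cells, against 2430 and 1250 CPM in HSC-like cells. In the old niche they were at 469 and 121 CPM in erythroid-like and 306 and 228 in T-cell-like cells, against 848 and 211 in HSC-like cells. An even level of free RNA does not account for the erythroid-like levels of the young niche, so free RNA may add to neutrophil transcripts in HSC-like cells but stays open.

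The second pattern is that Cdkn2a, Cdkn1a and Phlda3 were lower in the old niche libraries. With an equal mix of classes their median log2 fold stayed at -2.53, which argues against the shares of these classes as the whole cause. The classes join clusters that differ between libraries, so that test cannot exclude a change of mix within a class. Megakaryocyte-like cluster 3, for example, held 1505 and 437 cells of the young niche and 44 and 5 of the old niche. Among cells with Xist and no Y-linked UMI the median log2 fold of these genes was -3.65, which argues against the share of each sex as the whole cause. In HSC-like cells of young niche replicates 1 and 2 and old niche replicate 1, Phlda3 was at 25.7, 28.9 and 4.82 CPM in Xist cells but 9.37, 4.91 and 4.32 CPM in Y cells, and Cdkn1a at 35.2, 33.8 and 10.7 against 15.9, 14.2 and 8.64 CPM, with 3 and 6 UMIs in the last Y cells. After thinning, the share of cells with a UMI was higher in the young niche by a median factor of 5.48, which argues against depth. A change of mix within classes, a niche effect or another technical difference stays open and untested. For Hoxc6 the log2 fold in HSC-like Xist cells was -0.242 instead of -2.35, consistent with the share of each sex, but Y cells were at 33.4 and 46.6 CPM in the young niche and 4.32 CPM (3 UMIs) in old niche replicate 1, so the cause stays open.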

How the results depend on the processing

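Tests on cells with Xist and no Y-linked UMI, on clusters found in each library alone and without genes of free RNA were chosen only after the results were seen, as were the gene groups under further cell and cluster choices. A sign was read at 2 decimals. Where a result changed, the cause was not tested, except that leaving a library out changes the estimated spread by design. Of 80 named genes that passed in all kept cells, 29 passed in every setting, among them Cdkn2a, Cdkn1a, Phlda3, Mecom, Matn4, Dennd5b, Ctse and Gkn3. Of 20 in HSC-like cells, 5 did: AC168977.1, Cryab, Ctse, Gkn3 and Matn4. The groups hold 2 libraries each, so results lean on single libraries. With 1 library left out, the spread within groups comes only from the pair in the other group. In HSC-like cells the log2 ratio within a pair had an SD of 0.172 in the young and 0.447 in the old niche. Counts of changed genes with a library left out therefore also reflect the spread of the pair that is kept.

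The count of changed genes in all kept cells was 2101 with no low-count filter, 196 with a mean of at least 10 CPM and 2568 with a replicate block. It was 422 with at least 1000 genes per cell, 491 with thinned sums, 1477 with DESeq2 and 443 with limma. In HSC-like cells it was 134 without a scaling factor, 1064 with no low-count filter, 12 at 10 CPM and 1242 with a replicate block. It was 140 in cells with Xist only, 57 with clusters of thinned cells, 94 with clusters found in each library alone, 393 with DESeq2 and 71 with limma. In megakaryocyte-like cells it was 2461 with no low-count filter, 585 at 10 CPM, 2045 in cells with Xist only, 565 at resolution 1.0, 5 with clusters of thinned cells and 306 with clusters found in each library alone. It was 69 with thinned sums, 166 with DESeq2 and 6 with limma. With each library left out it ran from 381 to 6779 in all kept cells, 12 to 5588 in HSC-like cells and 73 to 4574 in megakaryocyte-like cells. The comparison of Xist and Y cells gave 53 to 1017 genes in HSC-like cells.

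Gene groups past the threshold with an estimated correlation were 0 in all kept cells and 0 in HSC-like cells, and by fry 3 and 0. With each library left out the HSC-like count ran from 7 to 16. Myeloid priming in all kept cells with Xist only turned upward, at an adjusted p of 0.597.

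Of genes that passed, Car1 turned to 0.464 in all kept cells with Xist only. The others below did not pass. In all kept cells with Xist only, Cd48 was at 1.49, Clu at -0.222 and Itga2b at -0.302. With at least 1000 genes per cell Mki67 was at 0.0145 and Procr at -0.0109. Clu was at -0.115 with a replicate block and -0.0343 with limma. In HSC-like cells Clu was at -0.0663 and -0.113 in these settings. Mki67 there was at -0.115 with Xist only and -0.135 with clusters found in each library alone. Slamf1 was at 0.0566 without a scaling factor, 0.0618 at 10 CPM, 0.0293 with at least 1000 genes per cell, 0.0057 without likely doublets, 0.0192 at resolution 1.0, 0.142 with clusters found in each library alone and 0.0216 with limma. Vwf was at 0.0418 with clusters found in each library alone.

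With each library left out in all kept cells, log2 folds ran from -1.64 to 0.432 for Cd48, -1.06 to 0.773 for Clu, -6.38 to 0.118 for Ddx3y, -1.21 to 0.173 for Fos and -0.0746 to 0.113 for Itga2b. They ran from -1.17 to 0.285 for Mki67, -0.0267 to 0.38 for Slamf1 and -0.381 to 0.00672 for Vwf. In HSC-like cells they ran from -1.08 to 0.844 for Clu, -0.123 to 0.112 for Slamf1 and -0.0161 to 1.0 for Hlf.

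Dendritic markers were at a log2 fold of -0.129 and B cell markers at -0.257 with at least 1000 genes per cell, mast cell markers at 0.149 with all barcodes and endothelial markers at -6.9e-05 in HSC-like cells with at least 1000 genes. The difference in the T-cell-like share was -0.101 points with clusters of thinned cells and -0.201 with at least 1000 genes per cell. For unnamed clusters it was 6.75 at resolution 1.0 and 14.3 with clusters found in each library alone.

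Differences in cells with a UMI, at 1000 UMIs, at 2500 UMIs and without thinning, were -1.96, -4.47 and -13.1 points for Cdkn2a and -8.14, -13.5 and -22.5 for Gkn3. They were 4.57, 9.32 and 4.67 for Dennd5b and 11.8, 19.7 and -0.957 for Mecom. For cells with at least 2 UMIs of the G2 and M phase group they were -17.0, -8.03 and -27.7 in all kept cells, and -30.3 without thinning in HSC-like cells.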

Other observations

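Apart from the edgeR comparison of HSC-like cells, all tests in this part were chosen only after the results were seen. That comparison was set beforehand, but Vps8 was picked from it afterwards.

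Each young niche library and old niche replicate 1 held cells with Xist and no Y-linked UMI beside cells with Y-linked UMIs and no Xist, so female and male cells could be compared within a library. In HSC-like cells of these 3 libraries, Gkn3 was at 197 and 201 CPM in Xist cells and 11.5 and 12.8 CPM in Y cells of young niche replicates 1 and 2. In old niche replicate 1 it was at 7.45 and 8.64 CPM. Cdkn2a was at 16.5 and 20.1 CPM in Xist cells against 3.54 and 2.94 in Y cells of the young niche libraries. Hoxc6 went the other way, at 4.77 and 1.86 CPM in Xist cells against 33.4 and 46.6 in Y cells of the young niche libraries, and so did Hoxc10, at 1.72 and 1.18 against 14.3 and 18.2. In old niche replicate 1, Hoxc6 was at 1.75 CPM in Xist cells and 4.32 CPM in Y cells (3 UMIs in 298 cells), and Hoxc10 and the Y cells' Cdkn2a had 0 UMIs.

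Beyond 6 sex-linked genes, 371 of 11303 tested genes differed between Xist and Y cells among HSC-like cells by edgeR with the library as a block, 179 higher in Xist cells and 192 higher in Y cells. Without young niche replicate 1, young niche replicate 2 or old niche replicate 1 the count was 53, 140 and 1017. Xist cells had more Inhba (log2 fold 2.50 ± 0.214, SE), Lgals1 (1.22 ± 0.0952), Phlda3 (1.74 ± 0.182), Cdkn1a (1.22 ± 0.132) and Vwf (0.773 ± 0.086). Y cells had more Meg3 (-1.70 ± 0.163), Cd34 (-1.07 ± 0.118) and the tight-junction gene Cldn5 (-1.07 ± 0.0944). Over all kept cells 643 genes beyond the 6 differed, and 2, 83 and 2095 when each library was left out in the same order. The labels give no sex, so the grouping rests on these transcripts, and cells of the 2 kinds may come from different animals of unlike history.

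Vps8, a subunit of an endosomal tethering complex, varied between cells more than its test shows. In HSC-like cells it was at 4.47 and 60.3 CPM in the young niche libraries and 754 and 658 CPM in the old niche libraries, and did not pass (log2 fold 4.49 ± 1.13, adjusted p = 0.13, edgeR). Vps8 (ENSMUSG00000033653) lies on chromosome 16 from 21423118 to 21644680. Among HSC-like cells, those with 5 or more Vps8 UMIs made up 12.1% and 13.9% of the old niche libraries, 1.88% of young niche replicate 2 and 0 of 5172 cells in young niche replicate 1, with up to 79 UMIs in a cell.

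For Vps8, free RNA was tested first by the share of such cells in HSC-like over neutrophil-like and erythroid-like cells. This gave a smaller ratio of 2.58, which does not decide, since 0 of 64 cells had to be set to 3 cells. A test by level was added after that. In the old niche library with the smaller ratio, the Vps8 level was 13.7 times higher in HSC-like than in those cells. This argues against free RNA as the whole cause in HSC-like cells. Neutrophil-like and erythroid-like cells together were also higher in the old niche, at 54.8 and 34.7 CPM against 3.24 and 4.43 in the young niche. Megakaryocyte-like cells were at 279 and 270 CPM against 3.82 and 44.4, so the rise was not limited to HSC-like cells. Cells with 5 or more UMIs were 1.14 times as frequent in Xist as in Y cells of old niche replicate 1 (Fisher's exact p = 0.501), which argues against cells of 1 sex in that library. In young niche replicate 2 they were 26 of 898 Xist cells (82.4 CPM) and 0 of 334 Y cells (21.6 CPM), so a link with sex stays open there. The 21 tested genes within 1 Mb had a median log2 fold of 0.00247, which argues against a gain of the whole region in most HSC-like cells. These folds are from sums over all HSC-like cells. A gain only in the 12.1% and 13.9% of old niche cells with 5 or more Vps8 UMIs could pass unseen, so that test cannot decide it. A clone of cells that differ at this locus, or reads assigned to it wrongly, may still give this pattern and was not tested.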
